A study of Mus musculus with 2 samples.

How the data were processed

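H3K27me3 ChIP-seq was measured in intestine of postnatal day 0 mice in 2 biological replicates, each a pool of animals of both sexes. Per the labels and the authors' notes deposited with the lists, each replicate's list covers technical replicates 1 and 2 together. The authors deposited 4 peak lists in narrowPeak format on mouse build mm10. Per those notes, the replicate lists were made from each replicate's filtered alignments and from control alignments, a list was made from both replicates' alignments together, and the replicated list was derived from the other 3. Replicate 1 was set against the control file used for replicate 2 and a second control file, and replicate 2 against the shared file alone. The peak caller, its version, the aligner and the threshold are not given in the sources used here. The lowest −log10 p in each list lay between 2.03 and 2.08.

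Each deposited list gives, per peak, the authors' fold enrichment over control, a linear ratio, and the authors' −log10 of the p-value and of the q-value. These are the authors' own values, and they were used only to describe, rank or filter peaks. The lists hold no reads, so depth per sample is unknown and no value was scaled between replicates. A list made from more reads, or against other control reads, can hold more weak peaks, so numbers of peaks depend on settings and depth that these lists do not carry. The caller's peaks were narrow (median length 252 bp in replicate 1, 314 bp in replicate 2 and 530 bp in the replicated list), although the mark forms broad domains, so domains were rebuilt by merging.

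Gene models were the protein-coding genes of GENCODE M21 on the 19 autosomes, X and Y, 21911 in all, on the same build as the lists, and the genome sequence was that of the GRCm38 reference. The TSS was the annotated 5′ end of the gene. Starts of other transcripts entered only an alternative count of marked genes, not the gene lists or the values of named genes. A gene was called marked when a peak of the replicated list overlapped the window of 1 kb on each side of its TSS. A promoter was called CpG-rich when a window of 500 bp within 1 kb of the TSS had a GC content of at least 55% and a ratio of observed to expected CpG of at least 0.75. Breadth at a gene was the percent of the 5 kb on each side of the TSS covered by a replicate's peaks, given as mean ± SD of the 2 replicates. Domains were peaks of the replicated list merged across gaps of up to 3 kb.

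The design held 1 group, so no comparison between conditions was made. Overlap of the replicates was set against 1000 random placements of the peaks on their own chromosomes, outside the unsequenced first stretch of each, as a one-sided test. Gene lists and CpG-rich promoters were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 18 lists and a threshold of 0.05. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only. The lists, written down before the data were examined, hold Hox genes, transcription factors of 3 other groups of organs, regulators and differentiation genes of the intestinal epithelium, gut mesenchyme and smooth muscle, enteric neurons and glia, blood and immune cells, endothelium, Wnt ligands, other developmental signals, Polycomb complexes, Ink4 genes, ribosomal proteins, housekeeping, germline and olfactory receptor genes. Genes are named by a rule also fixed then. From each list it takes the 2 marked genes with the broadest mean coverage and up to 2 members without a peak in either replicate, first by symbol. It adds the genes in the 10 longest domains and 18 genes named whatever their values. Members beyond that rule were named after their values were seen, where a count of marked or unmarked members was small.

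Alternatives were a −log10 q of at least 5, other overlap rules, equal numbers of peaks, placement within bins of 2 Mb, autosomes only, windows of 0.5 and 5 kb, at least 50% of the window covered, any annotated transcript start, a background of CpG-rich promoters, a lower CpG ratio of 0.65, merging gaps of 1 and 10 kb, the list called on pooled libraries, and each replicate's list alone. Those added after the data were seen were the peaks found in both replicates' lists, marked genes and gene lists without X, and overlap on X alone.

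The code was tested on simulated data. All of 200 seeded genes were found marked, 3.2% of 500 random gene lists passed an unadjusted p of 0.05, a randomly placed list overlapped replicate 1 at 1.01 times chance, and with 30% of peaks copied the measured overlap was 31.6% against 31.3% by construction. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.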

Results

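Trimethylation of lysine 27 of histone H3 (H3K27me3), the mark deposited by Polycomb repressive complex 2 on silenced genes, was mapped by ChIP-seq in whole intestine of mice at postnatal day 0. The series held 1 group of 2 biological replicates and no second tissue, age or treatment, so the measurements describe where the mark lay in newborn intestine and how far both replicates shared it. Replicate 1 was intestine from 15 pooled mice. Replicate 2 was also a pool, of a number of mice not given in the sources used here. Both pools held males and females. The replicate 1 list held 58809 peaks covering 22.1 Mb, and the replicate 2 list held 26827 peaks covering 13.6 Mb. The list that the authors called on both replicates together held 58920 peaks covering 28.0 Mb, and the authors' replicated list, which they derived from the other lists, held 19920 peaks covering 18.0 Mb, or 0.660% of the assembled chromosomes. The lists carry no read counts, so the sequencing depth behind each is unknown. All coordinates are those of mouse build mm10 (GRCm38).

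H3K27me3 lay at the start sites of a minority of genes. A peak of the replicated list lay within 1 kb of the transcription start site (TSS) of 2965 of 21911 protein-coding genes (13.5%), which are called marked genes from here on. The replicate 1 list marked 3759 genes and the replicate 2 list 2900, and 2633 genes were marked in both, against 498 if both sets were independent. Promoters rich in CpG dinucleotides carried the mark more often than the rest. Of 10634 CpG-rich promoters 1985 were marked (18.7%, 95% exact interval 17.9 to 19.4), and of 11277 other promoters 980 were marked (8.69%, 8.18 to 9.23), an odds ratio of 2.41 (Fisher's exact test, two-sided, p = 1.43e-104). Of the bases covered by the replicated list, 38.4% lay within 2.5 kb of a TSS, a zone that makes up 3.72% of the genome. Genes are not replicates, so this test and those on gene lists say how genes differ within these libraries, not how the mark varies between animals. Fisher's exact test also treats genes as independent. Neighbouring genes of any list or symbol group can share a domain, which can make its p-values too small.

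The Hox clusters, whose genes encode the transcription factors that pattern the body axis, held 4 of the 5 longest H3K27me3 domains in the genome. Of 39 Hox genes 38 were marked (97.4%, 95% exact interval 86.5 to 99.9), with 38 in each replicate, against 13.4% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted over 18 gene lists, adjusted exact p = 1.62e-31). Hoxa4 was the only member with no peak within 1 kb of its TSS in either replicate. Its TSS lies at position 52191753 of chromosome 6, in a stretch where peaks covered only 2.14% and 2.28% of the 5 kb on each side in replicates 1 and 2. The replicates' peaks covered 83.5% ± 0.136 (SD, n = 2) of the Hoxc cluster and 77.6% ± 0.0219 of the Hoxd cluster. Coverage was lower over the Hoxa cluster (51.5% ± 2.78) and the Hoxb cluster (45.8% ± 3.36). In these it was broadest at the TSSs of Hoxa10 (93.4% ± 2.42 of the 5 kb on each side) and Hoxb9 (92.2% ± 0.0212). The Hoxb cluster was taken over 174 kb, against 105, 116 and 96.8 kb for Hoxa, Hoxc and Hoxd. Its share includes the stretch between Hoxb13 and Hoxb9, where peaks from 96210531 to 96249307 of chromosome 11 were short and scattered. The broadest TSS coverage in the list was at Hoxd11 (96.5% ± 0.304 of the 5 kb on each side) and Hoxc12 (96.3% ± 0.474). At Hoxa13, Hoxb13 and Hoxd13, the posterior-most genes of their clusters, the same measure was 75.6% ± 2.54, 91.6% ± 1.75 and 89.2% ± 6.07. Several annotated Hox start sites are shared or belong to long read-through transcripts, such as those of Hoxd3 and Hoxd4 or of Hoxc5, and neighbouring genes lie in the same domain, so the members are not independent observations.

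**Figure D1:**
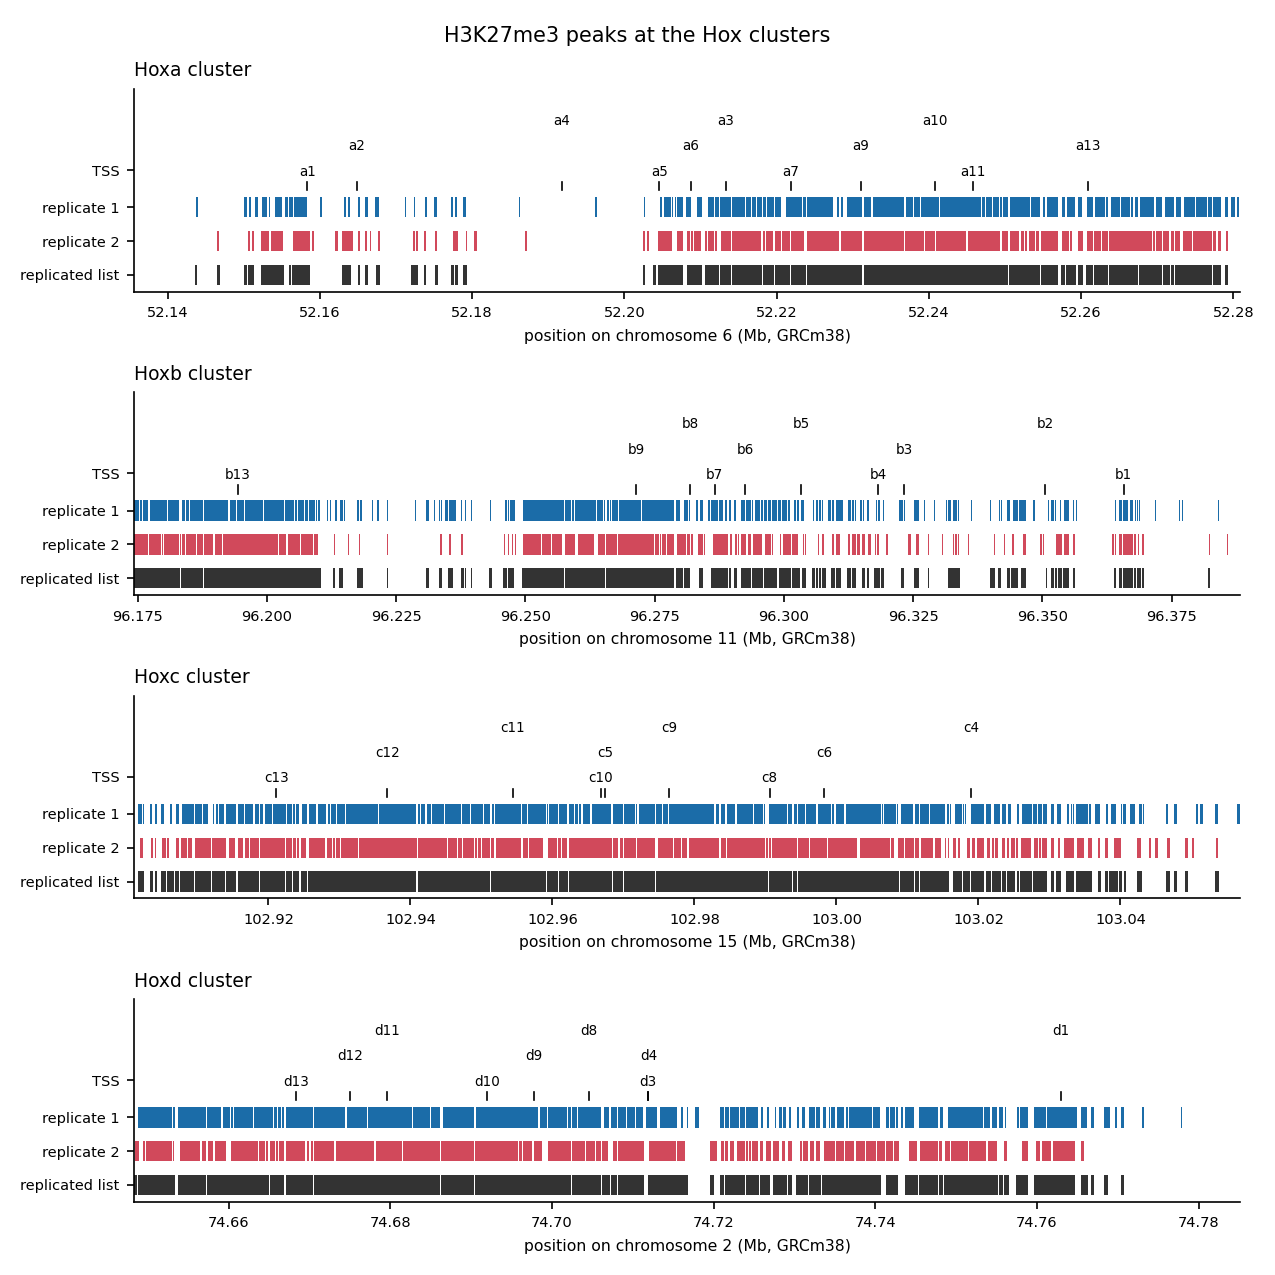
Peaks of replicate 1, replicate 2 and the authors' replicated list along the 4 Hox clusters, with position in Mb on the horizontal axis and ticks at the annotated TSSs (a1 stands for Hoxa1 and so on). Peaks cover most of Hoxc and Hoxd in both replicates, while few lie around Hoxa4.

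Merging peaks of the replicated list across gaps of up to 3 kb gave 505 domains of at least 10 kb, and developmental regulators held most of the longest. The longest domain ran for 148 kb over the whole Hoxc cluster (chromosome 15, 102894764 to 103043007). Next came 127 kb over Evx2 and the Hoxd cluster (chromosome 2, 74643448 to 74770735) and 91.8 kb over the TSS of Pax3, a regulator of neural crest and muscle precursors (chromosome 1, 78132597 to 78224385). Domains of 76.9 kb (chromosome 6, 52202455 to 52279343) and 76.3 kb (chromosome 11, 96243033 to 96319329) held Hoxa5 to Hoxa13 and Hoxb4 to Hoxb9. A further 68.8 kb covered the neighbouring genes Zic1 and Zic4, which act in the developing nervous system (chromosome 9, 91347369 to 91416164). Among the 10 longest were also 57.4 kb at Dmbx1 (chromosome 4, 115924952 to 115982380) and 57.2 kb at Nkx2-3, a regulator of gut mesenchyme (chromosome 19, 43567980 to 43625217). Only 2 of the 10 held no protein-coding TSS. A domain of 62.7 kb on chromosome 19 (44638500 to 44701214) lay 54.8 kb from the TSS of Pax2, and a domain of 59.0 kb on chromosome 9 (34960046 to 35019065) lay inside the gene Kirrel3. The replicate 1 list alone gave 810 domains of this length, the replicate 2 list 496, a merging gap of 1 kb gave 326 and a gap of 10 kb gave 897. With the gap of 10 kb the longest domain was instead 224 kb over the Hoxb cluster (chromosome 11, 96145860 to 96369734).

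Transcription factors listed for organs other than the intestine were mostly marked, though some of them, such as Pdx1, also act in intestine. All 39 transcription factors of brain and spinal cord were marked (adjusted exact p = 9.62e-34, 39 in each replicate), led by Olig2, a factor of oligodendrocytes and motor neurons, with 96.8% ± 0.311 of the 5 kb on each side of its TSS covered (SD, n = 2), and by Emx2, a factor of the cerebral cortex, with 94.5% ± 0.502. In the replicated list the Olig2 peak spanned 12639 bp (chromosome 16, 91217930 to 91230568), with its summit in the coding exon. Its fold enrichment was 8.92, against 9.26 and 7.09 for the peaks that replicates 1 and 2 held at this TSS. Pax6, which directs eye and brain development, had 92.9% ± 1.44 covered. Of 14 transcription factors of other endoderm organs 12 were marked (85.7%, adjusted exact p = 5.80e-09, with 12 and 13 in replicates 1 and 2). These included Pax9, a pharyngeal pouch factor (93.0% ± 3.64), Nkx2-1, a factor of lung and thyroid (90.7% ± 0.318), Sox2, a factor of oesophagus and stomach (88.6% ± 7.35), and Pdx1, a factor of pancreas and duodenum (55.8% ± 6.78). Trp63, a factor of stratified epithelia, and Pax4 were not marked, and Trp63 had no peak within 1 kb of the TSS in either replicate. That TSS is the annotated 5′ end of Trp63 (chromosome 16, 25683763), and starts further inside the gene, which reaches 25892102, were not examined. Of 19 transcription factors of skeletal muscle, heart and early mesoderm 15 were marked (78.9%, adjusted exact p = 6.14e-10, 15 in each replicate). Tbx15 had 90.6% ± 2.83 covered, Tbx20, a cardiac factor, 88.3% ± 2.18 and Myod1, a master regulator of skeletal muscle, 43.6% ± 1.32, while the neighbouring myogenic genes Myf5 and Myf6 had no peak within 5 kb of the TSS in either replicate.

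Lists of the intestine's mesenchyme, nerves, endothelium and epithelial regulators lay above other genes, and the list of epithelial differentiation genes did not pass the threshold. The lists were not tested against each other. Of 25 gut mesenchyme and smooth muscle genes 18 were marked (72.0%, adjusted exact p = 1.48e-10, with 20 and 18 in replicates 1 and 2), led by the transcription factors Barx1 (88.7% ± 5.67 of the 5 kb on each side, SD, n = 2) and Foxf2 (82.3% ± 10.5), with Foxf1, a key factor of gut mesoderm, at 75.5% ± 8.25. Of the smooth muscle genes in the list, Myh11, Cnn1, Des and Myocd were marked and Tagln was not, while Acta2 and Actg2 had no peak within 1 kb of the TSS in either replicate. Of 19 enteric neuron and glia genes 13 were marked (68.4%, adjusted exact p = 1.21e-07, with 14 and 12), led by Phox2b (85.6% ± 5.17) and Ascl1 (68.6% ± 3.72), both regulators of enteric neurons, and Nos1 and Plp1 had no peak. Of 13 endothelial genes 5 were marked (38.5%, adjusted exact p = 0.0340), led by Sox18 (71.8% ± 0.665) and Flt1 (55.4% ± 7.25), and Cdh5 and Emcn had no peak. The replicate 1 list marked 5 of them too, but against its higher background of 17.1% the adjusted p was 0.0789. Of 24 regulators of the intestinal epithelium 10 were marked (41.7%, adjusted exact p = 0.00117, with 14 and 11 in replicates 1 and 2). The widest coverage among them was at Gfi1, which acts in secretory cells (78.1% ± 4.07), and Foxa2 (70.7% ± 5.65). Cdx2, a master regulator of intestinal identity, had a peak of 723 bp in the replicated list within 1 kb of its TSS, inside the gene (chromosome 5, 147306189 to 147306911, summit in an intron). Replicates 1 and 2 covered 24.4% and 8.73% of the 5 kb on each side. Cdx2 had 66.1% and 23.3% of the 1 kb on each side covered. Its relative Cdx1 had a peak in each replicate's own list, at fold enrichments of 3.23 and 3.46, but none in the replicated list, and Hnf4a, a regulator of enterocyte genes, had no peak within 5 kb of the TSS in either replicate, nor had Creb3l3 and Ehf.

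Only 4 of 28 intestinal epithelial differentiation genes were marked (14.3%, adjusted exact p = 0.884, with 5 and 3 in replicates 1 and 2), close to the 13.5% of other genes. They were Chga, a marker of enteroendocrine cells (26.5% ± 1.28 of the 5 kb on each side, SD, n = 2), Cldn7, which had no peak within 1 kb of the TSS in the replicate 2 list, and Epcam and Cldn3. The Epcam peak was only 223 bp long (chromosome 17, 87636265 to 87636487, in an intron). The microvillus gene Vil1, the alkaline phosphatase gene Alpi and the goblet cell gene Agr2 had no peak within 5 kb of the TSS in either replicate. All 4 marked genes were among the list's 6 CpG-rich promoters, where 66.7% were marked against 18.6% of other CpG-rich promoters (adjusted exact p = 0.0216). Of 15 blood and immune genes 2 were marked (13.3%, adjusted exact p = 1.0), the transcription factor genes Pax5 (86.5% ± 0.106) and Tal1 (77.2% ± 5.85), with 5 and 2 in replicates 1 and 2. Cd79a and Cd8a had no peak. These 2 were the list's only CpG-rich promoters, and against other CpG-rich promoters their share was higher (adjusted exact p = 0.0482). Whole intestine is a mixed tissue, and a peak at a marker gene can come from any of its cell types.

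Most genes of developmental signals were marked. Of 19 Wnt ligand genes 17 were marked (89.5%, adjusted exact p = 9.64e-13, 18 in each replicate), led by Wnt10a (83.8% ± 1.45 of the 5 kb on each side, SD, n = 2) and Wnt1 (69.0% ± 7.06). Wnt8a and Wnt8b were the members outside the replicated list. Of 22 other signal genes 16 were marked (72.7%, adjusted exact p = 1.04e-09, with 18 and 17), led by Fgf8 (68.0% ± 5.90) and Fgf3 (60.3% ± 7.92), and Bmp2 and Bmp5 had no peak. The cell cycle inhibitor genes Cdkn2a and Cdkn2b, well-known Polycomb targets that lie side by side, were both marked. Around their annotated 5′ ends 70.8% ± 5.24 and 43.3% ± 0.580 was covered, and starts of other transcripts were not examined. This list of 2 passed the threshold (adjusted exact p = 0.0300), but not with the list called on pooled libraries (adjusted exact p = 0.0533). As neighbours at the same locus, the 2 genes are not independent observations, so the test overstates what they show. Of 25 genes of the Polycomb complexes themselves 4 were marked (16.0%, adjusted exact p = 0.884, 4 in each replicate), namely Cbx8 (54.2% ± 1.51), Pcgf1 (24.5% ± 2.19), Pcgf5 and Cbx2. Bmi1 and Cbx4 had no peak within 1 kb of the TSS in either replicate.

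Genes that every cell uses, and olfactory receptor genes, carried little of the mark. None of 16 housekeeping genes was marked in the replicated list or in either replicate's list, Actb, Gapdh and Eef1a1 included (95% exact interval up to 20.6%), a difference from other genes that the test could not resolve at this list size (adjusted exact p = 0.211). Of 30 ribosomal protein genes 1 was marked (3.33%, adjusted exact p = 0.223). It was Rpl3 (8.39% ± 1.56 of the 5 kb on each side, SD, n = 2), through a peak upstream of its TSS (chromosome 15, 80091920 to 80092928) that also lay within 1 kb of the TSS of the neighbouring gene Syngr1, at position 80091334. Rpl10a and Rpl11 had no peak within 5 kb of the TSS in either replicate. Of 11 germline genes 1 was marked (adjusted exact p = 1.0), namely Ddx4 (21.6% ± 1.36), and Dazl and Dppa3 had no peak. Of 1134 olfactory receptor genes only 8 were marked (0.705%, adjusted exact p = 2.84e-59), with 27 and 8 in replicates 1 and 2. The broadest coverage among them was at Olfr323 (29.4% and 35.3% of the 5 kb on each side in replicates 1 and 2) and Olfr332 (28.4% and 31.2%), and Olfr1 and Olfr10 had no peak. Of the 18 lists, 11 lay above other genes, 1 lay below and 6 did not pass the threshold.

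**Figure D2:**
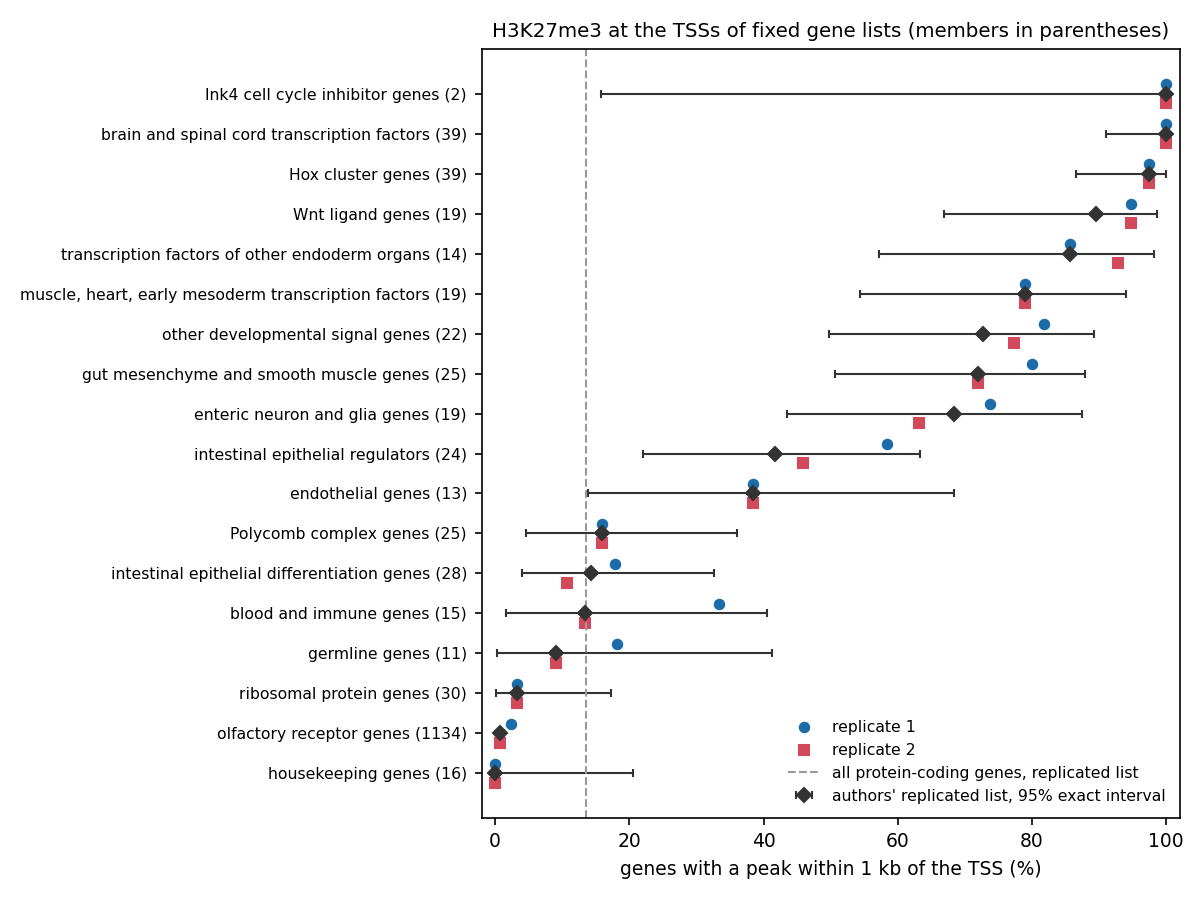
Percent of each fixed gene list with a peak within 1 kb of the TSS, in the authors' replicated list (diamonds, with 95% exact intervals) and in each replicate's own list (circles and squares), with the number of members in parentheses and the share of all protein-coding genes, 13.5%, as a dashed line. The Hox, Wnt and other-organ transcription factor lists lie between 78.9% and 100% in the replicated list, while olfactory receptor and housekeeping genes lie below 1%.

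On autosomes, strong peaks of either replicate mostly had a peak in the other, and weak ones often had none. Of replicate 2's peaks 64.9% were overlapped by at least 1 bp in replicate 1, and of replicate 1's peaks 30.1% were overlapped in replicate 2. Random placement of the same peaks on the same chromosomes gave 1.82% and 0.848%, and placement within bins of 2 Mb gave 4.44% and 2.10%. None of the 1000 placements of either kind came near the observed shares (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). On autosomes, 99.8% of replicate 1's peaks with a −log10 q of 10 or more were overlapped in replicate 2, 94.9% of those from 5 to 10, and 13.3% of those from 0 to 1. With both lists limited to a −log10 q of at least 5, the shares were 64.9% and 64.1% for replicates 1 and 2. On X, 52.1% of replicate 1's 48 peaks from 5 to 10 were overlapped, and 14.9% of its 389 peaks from 3 to 5. Replicate 2's X peaks in these classes were overlapped in replicate 1 in 80% of 10 and 77.6% of 49 cases. A q-value under 0.05 was reached by 75.3% of replicate 1's peaks and 84.7% of replicate 2's. At a −log10 q of 5 or more the lists held 4232 and 4195 peaks, so the difference in peak number lay among the weaker peaks. Across 17725 pairs of overlapping peaks, which are not independent replicates, Spearman's rho of fold enrichment was 0.392, and it was 0.518 over the 8028 pairs that shared at least 50% of each peak. Both replicates were called against a shared control library, which can add to their overlap. Of the 19920 peaks of the replicated list, 7810 (39.2%) lacked a peak sharing at least 50% of either length in both replicates' own lists, and 824 overlapped neither list.

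**Figure D3:**
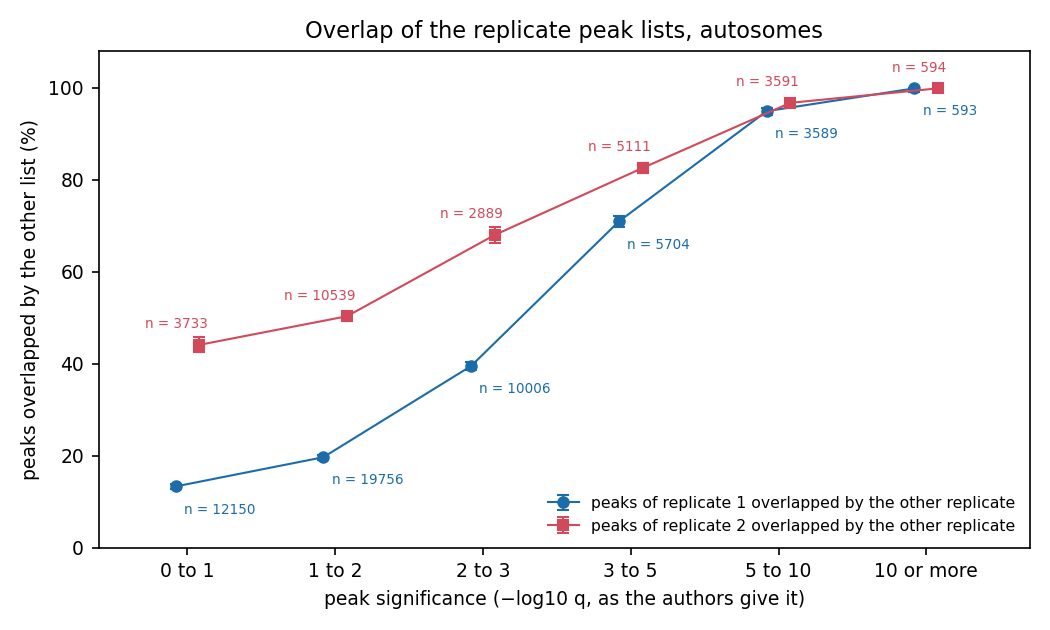
Percent of autosomal peaks of each replicate that overlap a peak of the other by at least 1 bp, by the peak's own −log10 q, with 95% exact intervals and the number of peaks in each class. Overlap rises with significance in both directions, from 13.3% to 99.8% for replicate 1 and from 44.1% to 99.8% for replicate 2.

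Among whole chromosomes, X was the one where the replicates' peak numbers differed most. It held 7011 of replicate 1's peaks (11.9%) and 370 of replicate 2's (1.38%), while it makes up 6.28% of the genome. That is 18.9 times as many in replicate 1, whereas on the 19 autosomes the ratio ran from 1.72 to 2.33, with a median of 1.97. Of 948 protein-coding genes on X, 197 (20.8%) were marked in replicate 1, 52 (5.49%) in replicate 2 and 77 (8.12%) in the replicated list. Only 8.57% of replicate 1's X peaks lay within 2.5 kb of a TSS, against 33.5% of replicate 2's, and against 23.6% and 34.6% of their autosomal peaks. Of replicate 1's X peaks 3.15% were overlapped in replicate 2, against 33.8% of its autosomal peaks. Replicate 2's short X list limits that share. In the other direction, 61.6% of replicate 2's X peaks were overlapped in replicate 1, against 65.0% of its autosomal peaks. With 2 libraries and no test between them, this is a difference between these libraries. Without X, 2888 genes were marked.

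**Figure D4:**
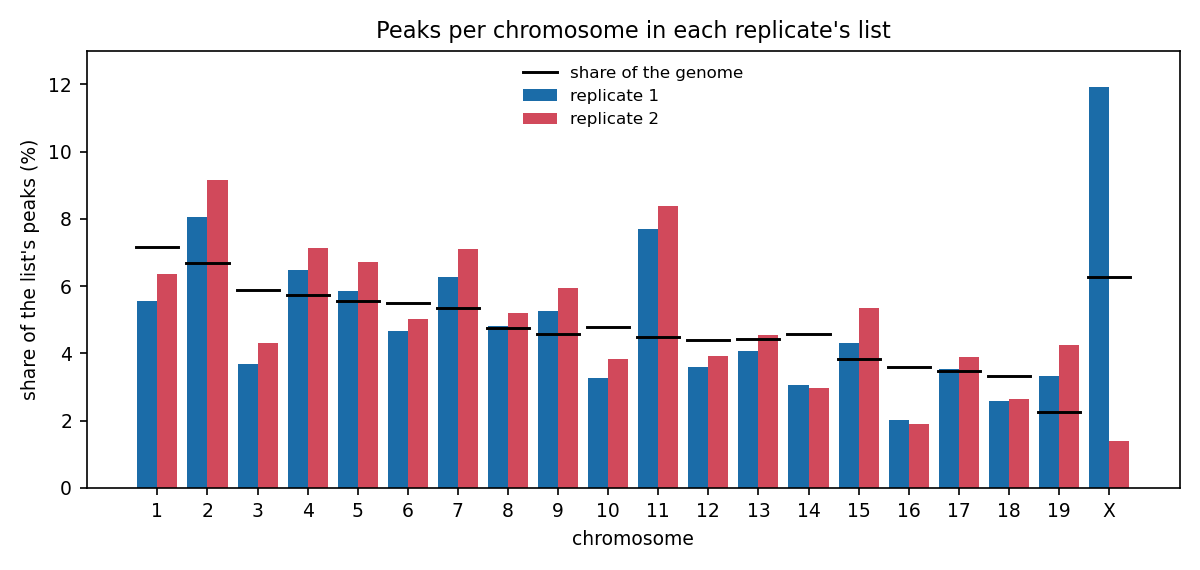
Share of each replicate's peaks on each autosome and X (bars), with the chromosome's share of the genome as a horizontal line. X holds 11.9% of replicate 1's peaks and 1.38% of replicate 2's, a contrast that no autosome shows.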

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

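All alternatives were chosen before the data were examined, except the peaks found in both replicates' lists, the marked genes and gene lists without X, and the overlap on X alone. The overlap of the replicates stayed above chance under every alternative run, and so did the odds ratio of CpG-rich promoters, from 1.74 to 3.84. Of the 18 gene lists, all kept their side of the threshold with windows of 0.5 or 5 kb, with 50% of the window covered, at a −log10 q of 5, without X, with peaks found in both replicates' lists, and with the replicate 2 list alone. Direction turned in 4 lists, none past the threshold in the replicated list. Epithelial differentiation genes lay below other genes at 17.9% with the pooled list, 3.57% at a −log10 q of 5 and with 50% of the window, 10.7% with 0.5 kb and 7.14% with peaks in both lists, and ranged from 10.7% to 17.9% with a replicate left out. Blood and immune genes lay above at 33.3% with the pooled list, 13.3% at a −log10 q of 5, with 0.5 kb, with 50% of the window and with peaks in both lists, 20% with 5 kb and 14.3% without X, and ranged from 13.3% to 33.3%. Polycomb genes lay below at 8.0% at a −log10 q of 5, 0% with 50% of the window and 17.4% among CpG-rich promoters, with 16.0% whichever replicate was left out. Germline genes lay above at 9.09% with 50% of the window and 20% among CpG-rich promoters, and ranged from 9.09% to 18.2%. The cause was not tested. Without replicate 2 the endothelial list no longer passed (38.5% marked either way, against a higher background), and with the pooled list the Ink4 genes did not (100% marked, adjusted exact p = 0.0533, again against a higher background). Against CpG-rich promoters alone, epithelial differentiation genes passed at 66.7% and blood and immune genes turned from level with other genes to above them at 100% (2 of 2 genes). No olfactory receptor gene has a CpG-rich promoter, so that list had no value there.

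Peak numbers depended most on the threshold. At a −log10 q of 5 the replicate 1, replicate 2, pooled and replicated lists held 4232, 4195, 9258 and 8960 peaks, and the first 3 covered 5.33, 5.27 and 12.8 Mb. The share of peaks within 2.5 kb of a TSS rose to 48.5%, 48.9%, 43.4% and 44.0%, and the share of bases to 45.8% in replicate 1 and 42.8% in the pooled list. Requiring 50% of the window left 1751 marked genes, and the other alternatives gave 2183 to 4132. Domains of at least 10 kb numbered 326 and 897 with gaps of 1 and 10 kb, and 496 to 810 with a replicate left out. X held 1.85% of the replicated list's bases, and 0.849% to 8.80% with a replicate left out. The correlation of fold enrichment was 0.518 over peaks sharing 50% of each, and the cause was not tested. Depth is unknown, so a missing peak does not show that the mark was absent. No paired analysis was possible because the series holds a single group.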

Other observations

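Tests chosen only after results were seen were the gene groups by symbol, the ratios of peak numbers above thresholds of significance and the comparison of peak positions at matched significance. All others in this part were written down before their results were seen.

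Several gene groups of which the fixed lists hold few members or none were also marked often. Protein-coding genes were grouped by the letters that open their symbol, and 357 groups with at least 8 members were tested as the gene lists were. Of these, 37 lay above other genes and 9 below (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The groups named here were chosen after their values were seen, and related groups did not all pass, such as Scn sodium channel genes (6 of 14, adjusted exact p = 0.0515) and Mmp metalloprotease genes (6 of 22, adjusted exact p = 0.359). All 8 Kcnh potassium channel genes were marked (adjusted exact p = 2.63e-06, with 8 and 7 in replicates 1 and 2), as were 7 of 8 Grm metabotropic glutamate receptor genes (adjusted exact p = 9.90e-05), 10 of 14 Htr serotonin receptor genes (adjusted exact p = 2.39e-05), 12 of 17 Syt synaptotagmin genes (adjusted exact p = 2.63e-06) and 9 of 14 Cacna calcium channel genes (adjusted exact p = 0.000245). Of 45 Col collagen genes 25 were marked (adjusted exact p = 2.52e-09, with 29 and 22), and of 19 Adamts extracellular protease genes 14 (adjusted exact p = 1.78e-07, 13 in each). The groups from Kcnh to Adamts stayed above others among CpG-rich promoters alone, with adjusted p from 4.15e-06 for Col to 0.0460 for Htr. Scn, which missed the threshold over all genes, passed there too (4 of 4 CpG-rich members marked, adjusted exact p = 0.0135). At the other end, none of 330 Vmn vomeronasal receptor genes (adjusted exact p = 1.71e-19), none of 49 Mrpl mitochondrial ribosome genes (adjusted exact p = 0.0121), none of 55 Eif genes (adjusted exact p = 0.00574), 1 of 67 Hist histone genes (adjusted exact p = 0.0102) and 19 of 394 Zfp zinc finger genes (adjusted exact p = 5.39e-07) were marked. Of the Vmn genes only 1 has a CpG-rich promoter, so among CpG-rich promoters that group had no support (adjusted exact p = 1.0), while Zfp, Eif, Hist and Mrpl stayed below others there, with adjusted exact p from 6.65e-05 for Zfp to 0.00358 for Mrpl.

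Marked and unmarked members of the 6 cell type marker lists differed in the CpG content of their promoters. Of 41 CpG-rich members 34 were marked (82.9%), and of 83 others 18 (21.7%), an odds ratio of 17.5 (Fisher's exact test, two-sided, p = 7.14e-11). Epithelial regulators had 8 of 12 and 2 of 12 marked and epithelial differentiation genes 4 of 6 and 0 of 22, the same share (66.7%) of CpG-rich members. With peaks found in both replicates' lists, 8 of the 24 regulators but only 2 of the 28 differentiation genes stayed marked. The equal shares therefore rest on few genes. Blood and immune genes had 2 of 2 and 0 of 13, endothelial genes 4 of 4 and 1 of 9, mesenchyme and smooth muscle genes 10 of 10 and 8 of 15, and enteric neuron and glia genes 6 of 7 and 7 of 12, a difference that did not pass in that list alone (exact p = 0.333). CpG content may therefore account for part of which markers carry the mark, as a hypothesis. Whether gene function accounts for the difference was not tested.

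Replicate 1's list held 2.19 times as many peaks as replicate 2's. More loci of the usual kind would, by the preset rule, lie near a TSS about as often as shared ones. Autosomal peaks that replicate 2 lacked lay within 2.5 kb of a TSS in 14.5% of cases against 41.5% of shared ones, a ratio of 0.348. The peaks replicate 1 held alone were also weaker (median −log10 q 1.33 against 2.96). With shared peaks weighted to the same −log10 q in replicate 1 the ratio was still 0.396 (bootstrap 95% interval over peaks 0.382 to 0.411). Sharing was decided by replicate 2's list, which can pick stronger loci than their −log10 q in replicate 1 shows. The ratios went against the preset expectation but cannot exclude weaker loci of the usual kind. At a −log10 q of at least 5 the ratio of peak numbers was 1.01 over all chromosomes and 0.999 on autosomes, where it was 1.96 over all peaks, and on X 50 and 10 peaks remained. Both lists admitted weak peaks, as 75.3% of replicate 1's and 84.7% of replicate 2's reached a q-value under 0.05. At that q-value 44275 and 22732 peaks remained, so peaks failing it do not by themselves account for the excess. The ratio was 1.76 at a −log10 q of at least 2 and 1.10 at 3. Whether weak peaks passing a q-value of 0.05 came from a permissive threshold stays open, since these counts raised the question. Depth and a true difference between the pools also stay open, as untested.

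The excess of X peaks in replicate 1 could reflect an offset of the whole X between ChIP and control, or H3K27me3 of the inactive X in female cells. At 221 shared X peaks the median log2 ratio of fold enrichment, replicate 1 over replicate 2, lay 0.14 above that on autosomes (bootstrap 95% interval 0.11 to 0.16). Among the higher-fold peaks, 78 of them on X, it lay 0.30 above. The first explanation thus reached its preset size of 0.2 in the stronger peaks but not over all. The interval covers sampling of peaks only, not variation between libraries. Across bins of 1 Mb on X, peaks of replicate 1 alone followed the density of TSSs (Spearman's rho 0.506), but autosomes ranged from 0.218 to 0.793, so X did not stand apart as the second explanation required. Both stay open and cannot be told apart here. The pools were of mixed sex and replicate 1 had a second control file, and neither a difference in their share of females nor the control was tested.

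The most significant peak of the replicated list lay on chromosome 17, over the long non-coding RNA gene Gm26917 (39843013 to 39846781 in the replicated list), and a neighbouring peak (39847984 to 39848905) overlapped an annotated ribosomal RNA gene. Their fold enrichment was 2.38 and 2.29, whereas 97 of the 100 most significant peaks of the replicated list had 7.05 to 10.3. The remaining peak with a low fold enrichment (4.72) lay in Cdk8 (chromosome 5, 146261001 to 146261478). Peaks at these places were among the 100 most significant of each replicate's own list, with a fold enrichment below 5 there too. Why they ranked so high was not tested, so they are not read as the strongest sites of the mark.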
